A study of Sus scrofa with 75 samples.

How the data were processed

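Whole blood collected in PAXgene tubes from 12 castrated pigs was profiled on one-colour (Cy3) Agilent porcine arrays, 1 blood sample per array and 75 arrays in all. Of the pigs, 6 came from a line selected for high residual feed intake (HRFI, the less feed-efficient line) and 6 from a line selected for low residual feed intake (LRFI, the more efficient line), and both were kept at 24 °C and then at 30 °C. The labels give 7 samplings: day -5 and day 0 at 09:00, both at 24 °C; day 0 at 13:00 and 18:00, after the temperature had been raised; and days 1, 2 and 13 at 30 °C. They do not give the hour of sampling on days -5, 1, 2 and 13. The number of pigs sampled was 6 HRFI and 6 LRFI at every sampling except day 0 at 09:00 (5 and 4) and day 13 (3 and 3).

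The deposited values carry no stated unit or log base and were treated as a normalized score per probe and array. Per the submitters' processing notes, Agilent Feature Extraction 10.10.1.1 and limma were used, without a statement of what each did. The deposited score had a mean between -0.01 and 0.01 and an SD between 0.952 and 1.05 on every array, medians between -0.15 and -0.11, a range of -2.95 to 4.32, and 0 missing values. Since the log base and the scaling are unknown, differences are given in deposited units, 1 unit being about 1 SD of all probes on an array, and no fold changes were computed. No probe was filtered and no array was left out. Background signal was not used here, so detection was not judged, and the number of arrays limits the precision of each mean.

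The table holds 32924 probes. Gene names were available only for the 358 probes whose identifier carries a RefSeq accession: 340 matched exactly 1 symbol of the Sscrofa11.1 gene table, and 18 matched none. The other probes carry manufacturer's or transcript identifiers that the files do not pair with a gene, so 32584 probes stayed unnamed. Every statement on genes or gene lists covers 340 genes, each with 1 named probe. No coordinates are given.

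Time comparisons were fitted with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8) on all 75 arrays, with pig as a fixed block and 1 coefficient per line and sampling, leaving 51 residual degrees of freedom. Each contrast is the mean of the changes of both lines, each sampling against day -5 and the 13:00 and 18:00 samplings against 09:00 of the same day; a moderated F-test covered all changes against day -5. Lines were compared on 1 value per pig, the mean over the 5 samplings that all 12 pigs have (day -5, day 0 at 13:00 and 18:00, days 1 and 2), and on the 12 arrays of day -5 alone, always as LRFI minus HRFI. Differences between the lines' changes were tested as line-by-time contrasts. P values were adjusted by Benjamini-Hochberg over all probes within a comparison, with a threshold of 0.05. The model, the comparisons, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Comparisons of days 1, 2 and 13 with 09:00 of day 0 were added afterwards.

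Of 25 gene lists, 13 had at least 3 measured members and were tested: glucocorticoid response (4 genes), immediate early genes (3), interferon-stimulated genes (11), inflammatory cytokines and NF-kB (11), acute phase genes of leukocytes (4), antioxidant NRF2 targets (4), lipid and fatty acid oxidation (6), markers of neutrophils (5), monocytes (7), T cells (6), platelets (4) and eosinophils and basophils (4), and energy-balance hormone signalling (4). A list's shift was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 13 lists of a comparison; members past the threshold were counted over all probes and adjusted over the list alone. Fry asks whether members move on balance in 1 direction and makes no comparison with other genes. The lists for heat shock and chaperones (HSP90AA1), endoplasmic reticulum stress (HSP90B1), glycolysis (GPI), cell cycle (BIRC5) and the proteasome (PSMC5 and PSMD4) had 1 or 2 members and are given as single genes. Another 2 lists had 1 member each, and these and some other genes are not reported here, though they stay in every count of probes. Circadian clock, oxidative phosphorylation, ribosomal protein, MHC class II and cytotoxic or NK cell lists had 0 measured members.

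Named genes are, in the comparisons of 13:00 and 18:00 with 09:00, of days 1 and 2 with day -5 and of the lines, up to 10 with the largest rise and 10 with the largest fall among named genes past the threshold that changed in that direction in at least 75% of the pigs with both samples. Elsewhere the 3 largest in each direction were taken, and in every comparison up to 4 called members per list. Where no probe passed, the 3 named genes with the smallest p are given as values. In the text, ± is the SD over pigs, and changes are model estimates with their standard error (SE).

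The labels mark each array with a repetition of 1 or 2 without saying what it is. It changes within pigs and follows time closely: 39 arrays carry repetition 1 and 36 carry repetition 2, and all but 1 of the 12 arrays of day -5 carry repetition 1 while 11 of the 12 at 13:00 carry repetition 2. Arrays were spread over 10 slides of 7 or 8. Deviations from the line-and-time means correlated at a mean of 0.356 between arrays of 1 pig and -0.041 between pigs, so the pig labels were used as given.

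Alternatives were pig as a random block or no block, slide or repetition as a covariate, arrays of 1 repetition only, the arrays of the compared samplings only, quantile normalization, median centring, array weights, trended and robust variances, omission of the probes with the lowest mean, tests of the 340 named probes only, other samplings in the pig mean, slide effects removed before pig means, and each pig left out in turn. Added after the data were examined were the omission of the 2 arrays least correlated with the rest, repetition removed before pig means, 1 repetition with only the compared samplings, and pen block as a covariate. Counts were also taken over up to 100 other splits of the pigs or samplings. The fit was tested on simulated data made from these arrays, with 200 of 32924 probes changed. Errors were drawn independently for each probe and without a repetition effect, so recovery in the real data may differ. Unchanged probes made up from 0.952% (lines) to 7.89% (18:00 against 09:00) of those called. At a change of 0.2 it recovered 70% of 50 changed probes for day 1 against day -5, 70% for 18:00 against 09:00 and 38% for the line comparison, and at 0.4 it recovered 98%, 96% and 76%. For the line difference in the change from 09:00 to 18:00 it recovered 12% at 0.2 and 64% at 0.4. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.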

Results

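The data collected were 75 array profiles of whole blood, 38 from 6 HRFI pigs and 37 from 6 LRFI pigs, followed through a rise in room temperature from 24 to 30 °C. HRFI pigs are the less feed-efficient line, eating more than their growth and maintenance predict, and LRFI pigs the more efficient one. Both lines gave 6 pigs at day -5, at 13:00 and 18:00 of day 0, and at days 1 and 2. At the remaining samplings 5 HRFI and 4 LRFI pigs gave blood at 09:00 of day 0, and 3 of each line at day 13. The series asks how blood expression responds to heat and whether lines that differ in feed efficiency respond differently. The samplings at day -5 and at 09:00 of day 0 were both unheated, so their difference is a background for reading changes at 30 °C. This background is not free of the repetition label, which was 1 on 11 of 12 arrays at day -5 and 2 on 7 of 9 at 09:00. Values are normalized array scores, with 1 unit near 1 SD of the probes on an array, and gene statements cover the 340 probes that could be named. Any 2 arrays correlated between 0.911 and 0.995.

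Over the whole course, 18432 of 32924 probes, 179 of them named, changed from day -5 at some sampling (limma, adjusted p under 0.05). Counts against day -5 were highest at 09:00 of day 0, before any heat, and at day 13. Only 45 probes separated 13:00 from 09:00 of the same day. At both of these samplings repetition 2 was the more frequent label, whereas most arrays of day -5 carried repetition 1. Counts that switch the label and counts that keep it are not alike, since 7021 probes differed between repetitions. Leaving out single pigs gave totals from 14090 to 18993.

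**Figure D1:**
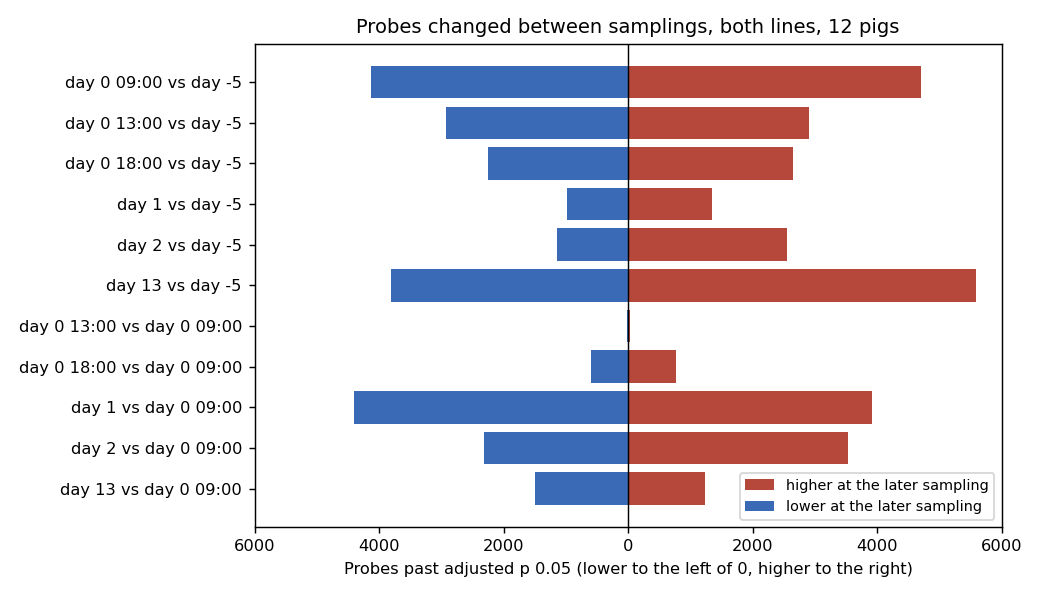
Number of probes past adjusted p 0.05 (horizontal axis, out of 32924) that were lower (left of 0) or higher (right of 0) at the later of 2 samplings, for 11 comparisons over both lines. The unheated 09:00 sampling of day 0 differed from day -5 by 4701 higher and 4130 lower probes, while 13:00 differed from 09:00 by 25 higher and 20 lower.

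The interval from 09:00 to 13:00 of day 0 spans the first hours after the temperature was raised. Over it, the transcript of the inflammatory cytokine IL1B fell from 0.30 ± 0.13 to -0.01 ± 0.09. The change of -0.32 (SE 0.05, limma adjusted p = 0.000695) was seen in 9 of 9 pigs. VPREB1, part of the surrogate light chain of the pre-B cell receptor, fell by 0.21 (adjusted p = 0.0370), from 0.51 ± 0.25 to 0.31 ± 0.20, in 9 of 9 pigs. These were the only named genes among the 45 probes that changed. Monocyte markers were lower as a list, with a median change of -0.09 over 7 genes (camera adjusted p = 0.0001, and adjusted p = 0.0633 with an estimated correlation). None of the 7 passed over all probes and 5 fell when adjusted over the list alone. Lysozyme (LYZ) differed by -0.24 (adjusted p = 0.143), the haemoglobin scavenger receptor CD163 by -0.20 (0.337) and FGL2 by -0.16 (0.136). The inflammatory cytokine and NF-kB list had a median of -0.11 (camera adjusted p = 0.000213, and adjusted p = 0.0633 with an estimated correlation), with 1 of 11 genes lower over all probes and 2 adjusted over the list alone. Eosinophil and basophil markers went the other way, with a median of 0.16 over 4 genes (camera adjusted p = 0.00243, and adjusted p = 0.115 with an estimated correlation). None passed over all probes and 2 rose adjusted over the list alone, while another member changed by a mean of -0.02 in each line. HSP90AA1, the stress-inducible cytosolic chaperone and the sole measured gene of the heat shock list, differed by 0.03 (adjusted p = 0.75). IL1B passed with each pig left out, its highest adjusted p being 0.00741. The count itself was 45 without HRFI pig 4325 too but moved with the other 11 pigs: without HRFI pigs 3386, 3394, 4323, 4447 and 4462 it was 409, 23, 7, 23 and 5. Without LRFI pigs 3357, 3371, 4307, 4370, 4381 and 4420 it was 9, 27, 214, 7, 5 and 15. Hour of day moved together with temperature, and among the arrays of repetition 2, where 6 pigs have both samples, 9 probes passed.

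By 18:00, genes of eosinophils had risen over 09:00. The arachidonate lipoxygenase gene ALOX15 went from 0.92 ± 0.16 to 1.15 ± 0.16 (change 0.26, SE 0.05, limma adjusted p = 0.00471) and CCR3, the eotaxin receptor, from 0.39 ± 0.18 to 0.63 ± 0.23 (0.26, SE 0.06, adjusted p = 0.00945), each higher in 9 of 9 pigs. Against day -5, the other unheated sampling, they differed at 18:00 by 0.05 (adjusted p = 0.528) and 0.07 (adjusted p = 0.391). Their list had a median of 0.22 (camera adjusted p = 0.00355, and adjusted p = 0.128 with an estimated correlation), with 2 of 4 members higher over all probes and 3 adjusted over the list alone. HRH4 differed by 0.18 (adjusted p = 0.177). The remaining member changed by a mean of 0.02 in HRFI and -0.01 in LRFI pigs, so the list's rise rests on the other members. HSP90AA1 rose by 0.09 (SE 0.03, adjusted p = 0.0445), from 1.64 ± 0.13 to 1.72 ± 0.11 in 8 of 9 pigs, whereas the endoplasmic reticulum chaperone HSP90B1 differed by -0.01 (adjusted p = 0.940). Smaller rises were called for PLCD4 and CALCB (0.19 each), the cathepsin gene CTSK (0.16), POU2F1 (0.10) and the cytokine gene TGFB1 (0.09), in 8 or 9 of 9 pigs, with adjusted p between 0.0204 and 0.0361.

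Other transcripts fell over the same hours. Thioredoxin (TXN) dropped from 1.37 ± 0.08 to 1.18 ± 0.09 (change -0.21, SE 0.05, limma adjusted p = 0.00972) and LYZ from 2.00 ± 0.17 to 1.76 ± 0.19 (-0.24, SE 0.07, adjusted p = 0.0445), each in 9 of 9 pigs. The pattern receptor TLR2 fell by 0.17 (adjusted p = 0.0457), the Fc receptor FCGR3A by 0.15 (0.0266) and the glutaredoxin GLRX by 0.14 (0.0150), all in 9 of 9 pigs. So did the myeloid and NK cell adaptor TYROBP, by 0.13 (0.0485), and the adhesion molecule ICAM2, by 0.12 (0.0144). CHI3L1, ST8SIA4 and the chemokine gene CCL3L1 fell by 0.17, 0.17 and 0.16 in 8 of 9 pigs. Among lists, the monocyte markers (median -0.09, camera adjusted p = 0.0141), the inflammatory list (-0.11, 0.0160) and the antioxidant list (-0.15, 0.0160) were lower. With an estimated correlation these were adjusted p = 0.235, 0.235 and 0.128. Over all probes 1, 2 and 1 of their members fell, and 2, 2 and 2 adjusted over the list alone. In all, 1379 probes changed, 776 higher and 603 lower, 18 of them named. Without HRFI pig 3386 or 4462 the count was 807 or 728, and without LRFI pig 3357, 4370, 4381 or 4420 it was 732, 574, 92 or 461. ALOX15 and CCR3 were the 2 of 18 named genes called with each pig left out. CCR3 was lost with pig as a random block, and neither passed without a block for pig (adjusted p = 0.217 and 0.444). Among the arrays of repetition 2, where 6 pigs have both samples, both passed (limma adjusted p = 0.0159 and 0.0154). With only those of the compared samplings, and so fewer arrays, they changed by 0.26 and 0.24 without passing (limma adjusted p = 0.0824 and 0.0927), and limma called 0 probes (5881 at an unadjusted p under 0.05). LYZ, FCGR3A, TLR2, CHI3L1 and TYROBP did not pass after quantile normalization, and HSP90AA1 not with slide as a covariate.

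**Figure D2:**
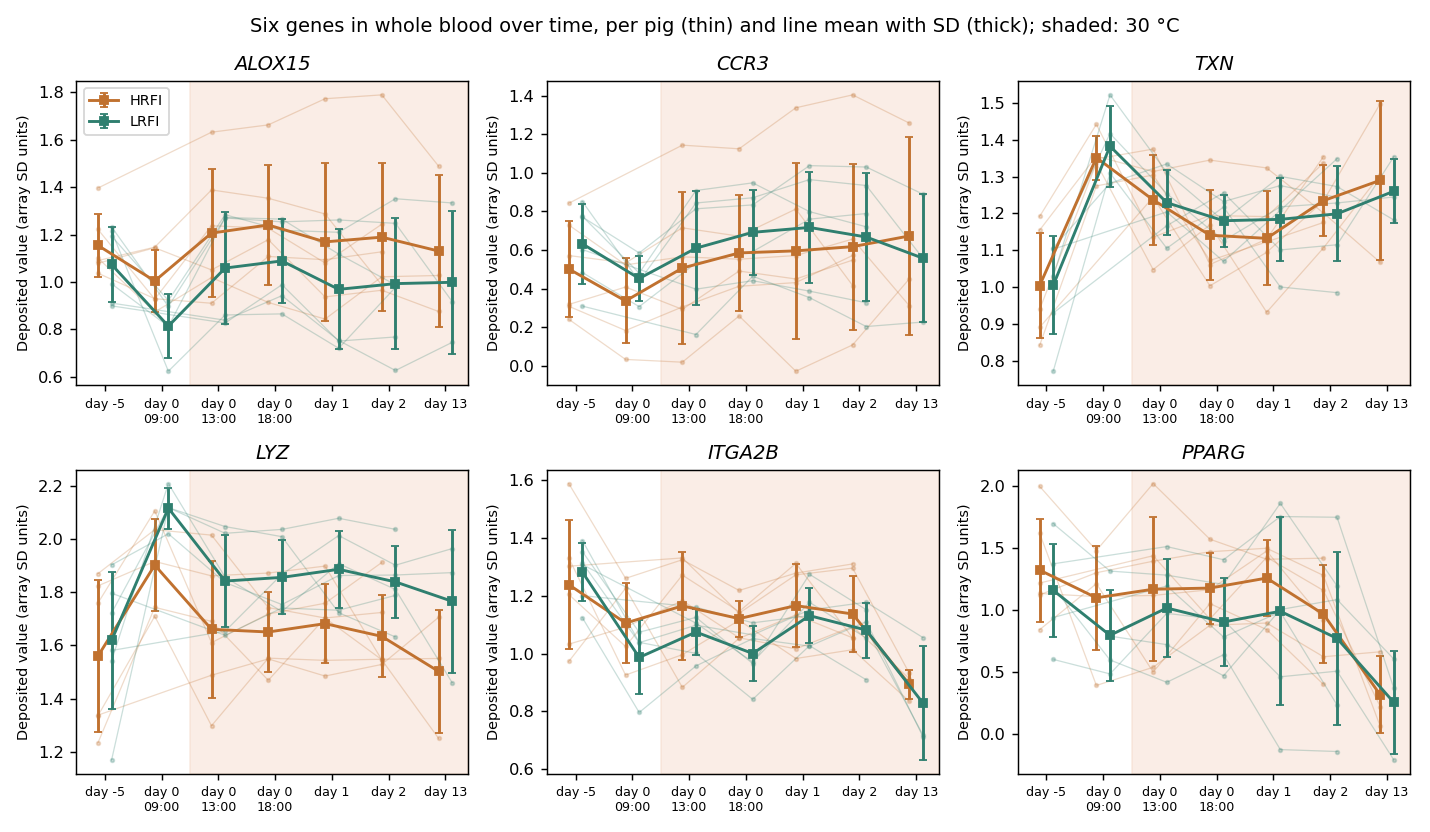
Deposited value (vertical axis, array SD units) of ALOX15, CCR3, TXN, LYZ, ITGA2B and PPARG at the 7 samplings, with 1 thin line per pig and squares with SD bars for the mean of each line (3 to 6 pigs); shading marks 30 °C. TXN and LYZ stood at 1.37 and 2.00 at 09:00 of day 0 and at 1.18 and 1.76 at 18:00 in the 9 pigs with both samples, and PPARG was lowest at day 13.

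The background between the unheated samplings was large. At 09:00 of day 0, before heat, the interferon-inducible checkpoint ligand CD274 stood 0.66 above day -5 (SE 0.16, limma adjusted p = 0.00157, 7 of 9 pigs), the Fc receptor FCGR1A 0.53 (0.00202, 8 of 9), LYZ 0.40 (2.27e-05, 9 of 9) and TXN 0.36 (9.76e-08, 9 of 9). The interferon-stimulated genes RSAD2 and EIF2AK2 rose by 0.36 and 0.16, and CXCL10 by 0.53 (adjusted p = 0.0476) in 6 of 9 pigs. Of that list's 11 members 4 rose both over all probes and adjusted over the list alone (median 0.13, camera adjusted p = 0.396). Monocyte markers were higher (median 0.15, camera adjusted p = 0.0269, and adjusted p = 0.592 with an estimated correlation), with 4 of 7 higher over all probes and 5 adjusted over the list alone. Platelet genes were lower: ITGA2B, SELP and ITGB3 fell by 0.20, 0.21 and 0.21, making 3 of 4 members by both counts (median -0.21, camera adjusted p = 0.0443, and adjusted p = 0.592 with an estimated correlation). Also lower were ALOX15 (-0.21, adjusted p = 0.00210, 7 of 9 pigs), CCR3 (-0.18, adjusted p = 0.0136, 8 of 9), the transcription factor MYC (-0.21, adjusted p = 9.76e-05, 9 of 9), JUP (-0.27) and CTSK (-0.24). A total of 8831 probes differed, 4701 higher and 4130 lower, 106 of them named. The immediate early list had a median of 0.03 but a mean of -0.04, and its test pointed down (camera adjusted p = 0.596). With only the arrays of both samplings in the fit, 2891 probes were called.

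At 13:00 against day -5, CD274 (0.53, SE 0.15, limma adjusted p = 0.00947) and the cytokine IL15 (0.28, SE 0.07, adjusted p = 0.00228) were higher in 9 of 12 pigs each, FCGR1A was higher by 0.34 (0.0409) and B3GALNT1 lower by -0.25 (0.00416). The neutrophil chemokine CXCL8 fell by 0.35 (SE 0.10, adjusted p = 0.00890) in 11 of 12 pigs and IL1B fell by 0.30 (SE 0.05, adjusted p = 6.73e-06) in 12 of 12. At 18:00, CXCL8 was lower by -0.33 (adjusted p = 0.0180) in 10 of 12 pigs, the aminopeptidase ANPEP by -0.25 (adjusted p = 0.0181) in 10 and JUP by -0.23 (adjusted p = 0.000158) in 12. CD274 (0.45, adjusted p = 0.0343) and IL15 (0.20, adjusted p = 0.0366) were still above day -5 in 9 pigs each. The T and NK cell adaptor SH2D1A (0.23, adjusted p = 0.00304) and HSP90AA1 (0.09, adjusted p = 0.0156) were higher in 11 each. Platelet genes ITGA2B, ITGB3 and SELP fell by 0.20, 0.18 and 0.15 at 18:00, 3 of 4 members by both counts (median -0.17, camera adjusted p = 0.0124, and adjusted p = 0.718 with an estimated correlation). The interferon list at 18:00 had a median of -0.03 and a mean of 0.06 (camera adjusted p = 0.788). In all, 5832 probes changed at 13:00 (2909 higher, 2923 lower) and 4906 at 18:00 (2653 higher, 2253 lower). Without HRFI pig 3386 the 13:00 count was 3715.

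At day 1, some monocyte transcripts were above day -5, as they had been before heat at 09:00 of day 0. The monocyte list's median was 0.15 at 09:00, and LYZ and TXN each fell by 0.21 from 09:00 to day 1. CD163, a scavenger receptor that glucocorticoids induce, rose from 0.44 ± 0.30 to 0.69 ± 0.27 (change 0.25, SE 0.08, limma adjusted p = 0.0423, 9 of 12 pigs). The costimulatory ligand CD86 rose by 0.12 (adjusted p = 0.0267, 9 of 12), and LYZ differed by 0.19 (adjusted p = 0.0568). The monocyte list had a median of 0.12 (camera adjusted p = 0.00281, and adjusted p = 0.40 with an estimated correlation; fry adjusted p = 0.00796), with 2 of 7 members higher over all probes and 5 adjusted over the list alone. CCL3L1 rose by 0.20 (SE 0.04, adjusted p = 0.00869) in 9 of 12 pigs, TXN by 0.15 (adjusted p = 0.0259) in 10 and FCGR3A by 0.15 (adjusted p = 0.0147) in 9. HSP90B1 went from 1.43 ± 0.09 to 1.53 ± 0.07 (0.10, SE 0.03, adjusted p = 0.0357) in 10 of 12 pigs, while HSP90AA1 differed by 0.07 (adjusted p = 0.0809). NAMPT, HMGB1, ID2 and the T cell costimulator ICOS rose by 0.23, 0.15, 0.13 and 0.13.

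Genes that fell at day 1 included F12 and PROC. Coagulation factor XII (F12) dropped from 0.61 ± 0.18 to 0.46 ± 0.20 (change -0.16, SE 0.04, limma adjusted p = 0.0183) and protein C (PROC) fell by 0.16 (SE 0.05, adjusted p = 0.0418), each in 10 of 12 pigs. The lipase inhibitor ANGPTL4 fell by 0.12 (adjusted p = 0.0114), the junction protein JUP by 0.14 (0.0267), TRO by 0.11 (0.0383) and GATA3 by 0.09 (0.0341), in 9 or 10 of 12 pigs. Between day -5 and day 1, 1350 probes rose and 975 fell, 2325 in all with 28 named. This was a smaller number than between the unheated samplings, which mostly differ in repetition label while day 1 and day -5 mostly share it. With repetition as a covariate both counts stayed within 1.5 times the reported ones, so the gap between them remained. The count was 3602 without HRFI pig 3386, 890 without 3394, 454 without 4325 and 1132 without 4447. Without LRFI pigs 4307, 4370 and 4381 it was 1149, 273 and 705, and CCL3L1 alone of the 16 genes named here passed with every pig left out (highest adjusted p 0.0352). Among the arrays of repetition 1, where 10 pigs have both samples, 804 probes passed, and with only those of the compared samplings 0 did (4273 at an unadjusted p under 0.05). From all 12 pigs, with only the arrays of the compared samplings in the fit, 0 probes passed with limma. After quantile normalization more of the called probes were lower than higher.

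At day 2, TXN and HSP90B1 were again above day -5. TXN went from 1.00 ± 0.13 to 1.22 ± 0.11 (change 0.21, SE 0.04, limma adjusted p = 0.00123) in 12 of 12 pigs and HSP90B1 rose by 0.11 (SE 0.03, adjusted p = 0.00930) in 11, while HSP90AA1 differed by 0.02 (adjusted p = 0.610). The microsomal glutathione transferase MGST1 rose by 0.15 (SE 0.03, adjusted p = 0.00276, 11 of 12) and the interleukin receptor IL18R1 by 0.13 (adjusted p = 0.0108, 11 of 12). PTH1R, NAMPT, SH2D1A, ST8SIA4, CD86 and FCGR3A rose by 0.26, 0.22, 0.18, 0.14, 0.13 and 0.12. No list passed camera; the monocyte markers had a median of 0.07 (camera adjusted p = 0.409), with 1 of 7 higher over all probes and 2 adjusted over the list alone.

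The nuclear receptor PPARG, the receptor BMPR1B and ACR showed the largest falls at day 2 among named genes, by 0.37 (SE 0.13, limma adjusted p = 0.0451, 10 of 12 pigs), 0.35 (SE 0.12, 0.0458, 9 of 12) and 0.32 (SE 0.11, 0.0425, 9 of 12). The embryonic globin HBE1 fell by 0.20 (adjusted p = 0.0261) and the adiponectin receptor ADIPOR1 by 0.16 (adjusted p = 0.0488), in 11 and 9 of 12 pigs. F12 and PROC fell by 0.19 (adjusted p = 0.00192, 11 of 12) and 0.16 (adjusted p = 0.0319, 9 of 12), TRO by 0.18 (0.000862), JUP by 0.16 (0.00615) and ANGPTL4 by 0.11 (0.00841), these last in 11 of 12 pigs each. The neutrophil gelatinase MMP9 went from 1.74 ± 0.33 to 1.56 ± 0.37 (-0.19, SE 0.05, adjusted p = 0.0203, 11 of 12), and the platelet integrin ITGA2B fell by 0.15. A total of 3686 probes changed, 2551 higher and 1135 lower, 43 named. Without HRFI pig 4325 it was 2054, and without LRFI pigs 4307 and 4370 it was 2297 and 1650. With every pig left out in turn, 8 of the 22 genes named here passed: TXN, MGST1, IL18R1, F12, TRO, JUP, HSP90B1 and ANGPTL4. With repetition as a covariate 7077 probes were called, and within repetition 1, where 8 pigs have both samples, 1173.

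At day 13, PPARG, BMPR1B and ACR were far below day -5. PPARG went from 1.18 ± 0.34 to 0.28 ± 0.33 (change -0.97, SE 0.16, limma adjusted p = 7.37e-06), BMPR1B from 0.48 ± 0.30 to -0.43 ± 0.31 (-0.95, SE 0.15, adjusted p = 4.01e-06) and ACR from 1.00 ± 0.31 to 0.25 ± 0.29 (-0.81, SE 0.13, adjusted p = 8.91e-06), each in 6 of 6 pigs. HBE1 and ADIPOR1 were lower by -0.37 and -0.33. Platelet genes fell in 6 of 6 pigs: ITGA2B from 1.22 ± 0.12 to 0.86 ± 0.13 (-0.38, SE 0.05, adjusted p = 6.40e-07), ITGB3 by 0.35 (SE 0.05) and SELP by 0.34 (SE 0.06). Their list had a median of -0.34 (camera adjusted p = 0.000201, and adjusted p = 0.251 with an estimated correlation), with 3 of 4 members lower by both counts. T cell genes were higher, CD2 by 0.21, CD3G and CD8A by 0.18 and CD3E by 0.11, all in 6 of 6 pigs. Of 6 members 4 rose by both counts, with a list median of 0.14 (camera adjusted p = 0.114, fry adjusted p = 0.00125). PTH1R rose by 0.48 (SE 0.11, adjusted p = 0.000909) and SH2D1A by 0.35 (SE 0.07, adjusted p = 0.000106) in 6 of 6 pigs, and OASL by 0.31 in 5. BIRC5, an inhibitor of apoptosis active in dividing cells, rose by 0.25 and the proteasome ATPase PSMC5 by 0.12, while C-reactive protein (CRP) and MMP9 fell by 0.30 and 0.27. Of the immediate early genes, KLF4 and MYC fell by 0.19 and 0.15. The interferon, inflammatory and antioxidant lists had medians of 0.06, 0.01 and 0.00 while camera pointed down (adjusted p = 0.949 for each). In all, 9385 probes changed, 5584 higher and 3801 lower, 106 named. The pigs were also older than at day -5, and 4122 probes passed when only the arrays of both samplings were fitted.

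Read against the other unheated sampling, 09:00 of day 0, days 1, 2 and 13 gave other directions for some genes. Among them were TXN and LYZ, which each fell by 0.21 at day 1. FCGR3A differed by -0.14 at day 1 and by -0.17 at day 2. Repetition 2 was on 7 of 9 arrays at 09:00, and repetition 1 on 11 of 12 at day 1 and 9 of 12 at day 2. The comparisons of days 1 and 2 with 09:00 thus mostly switch the label too. CD274 was lower by -0.43 (SE 0.16, limma adjusted p = 0.0454, 8 of 9 pigs), FCGR1A by -0.37 (adjusted p = 0.0359, 9 of 9) and the activation marker CD69 by -0.21 (adjusted p = 0.000316, 8 of 9). CCR3 was higher at day 1 by 0.27 (adjusted p = 0.000424, 8 of 9) and at day 2 by 0.26, the plasminogen activator PLAU by 0.34 and 0.27, and B3GALNT1 by 0.26 and 0.24. HSP90AA1 was higher by 0.08 at day 1 (adjusted p = 0.0440, 8 of 9). At day 2, the calpain small subunit CAPNS1 (-0.41, adjusted p = 0.0199, 7 of 9), ATP4B (-0.26) and LYZ (-0.26, adjusted p = 0.0103, 9 of 9) were lower. PPARG rose in HRFI pig 4447 (0.39 to 0.62) and LRFI pigs 4381 (0.48 to 0.51) and 4420 (0.79 to 1.08). It fell in the other pigs with both samples, most in HRFI pig 3386 (1.21 to 0.40) and LRFI pig 4370 (0.60 to -0.14). ITGA2B rose in all pigs with both samples except HRFI pig 3386 (1.23 to 1.05) and LRFI pig 4370 (1.04 to 0.91). The day 2 fall of ITGA2B given above was thus not seen against 09:00. At day 13, where 4 pigs have both samples, the model over all arrays gave -0.73, -0.70 and -0.63 for PPARG, BMPR1B and ACR. For PTH1R, CD8A and DNASE1 it gave 0.37, 0.24 and 0.17. Within those 4 pigs, PPARG fell from 1.30 to 0.06 (HRFI pig 4323), 0.48 to -0.21 (LRFI pig 4381) and 0.79 to 0.60 (LRFI pig 4420). In HRFI pig 4447 it rose from 0.39 to 0.66. Counts were 8315 at day 1 (3916 higher, 4399 lower), 5843 at day 2 (3533 higher, 2310 lower) and 2727 at day 13 (1229 higher, 1498 lower). After median centring more of the day 2 probes were lower than higher. With only the arrays of the compared samplings in the fit, 0 probes passed at day 13. No list passed camera at days 1 and 2. At day 13 the T cell list (median 0.10, camera adjusted p = 0.0334) was higher and the neutrophil (-0.10, 0.0266), platelet (-0.13, 0.0266), monocyte (-0.07, 0.0334) and antioxidant (-0.10, 0.0479) lists lower. With an estimated correlation these were adjusted p = 0.281, 0.258, 0.281, 0.281 and 0.258. Adjusted over the list alone 3 T cell genes rose, and 2 neutrophil, 2 platelet, 1 monocyte and 1 antioxidant gene fell. Over all probes the numbers were 2, 1, 1, 1 and 1. Without LRFI pig 4381 the day 2 count was 3533 and the day 13 count 8. The day 13 count was also 1600, 971, 511 and 6869 without HRFI pigs 3386, 3394, 4323 and 4447, and 1118 without LRFI pig 3371. None of the 13 genes named at day 13 passed with every pig left out.

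Lists that passed camera in none of the time comparisons are given for days 1 and 2 against day -5. Glucocorticoid response genes had medians of 0.07 and 0.05 (camera adjusted p = 0.171 and 0.614), with CD163 called at day 1 and 0 genes at day 2 over all probes. Adjusted over the list alone 2 rose at day 1, and at day 2 1 rose and 1 fell. Immediate early genes had medians of -0.02 and -0.06 (0.719 and 0.497), interferon-stimulated genes 0.04 and 0.07 (0.386 and 0.575), and lipid genes -0.04 and -0.05 (0.555 and 0.497). Acute phase genes had medians of 0.01 and -0.07 (0.856 and 0.497) and hormone signalling genes 0.00 and 0.00 with means of -0.01 and -0.03 (0.904 and 0.614). The glycolytic enzyme GPI and the proteasome subunits PSMC5 and PSMD4, the measured genes of their lists, were not called at either day. Median, mean and test also differed in sign, with none passing camera, for T cell genes at 09:00 and 18:00, monocyte genes at 13:00, and antioxidant and hormone signalling genes at 18:00 against day -5. The same held for neutrophil, eosinophil and hormone signalling genes at day 1 and eosinophil and hormone signalling genes at day 2. Against 09:00 it held for lipid genes at 13:00, hormone signalling genes at 18:00, immediate early and acute phase genes at day 1, and immediate early and eosinophil genes at day 13.

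The probe for CAPNS1, the calpain small subunit, gave a far lower signal in LRFI than in HRFI pigs. Its lowest value, -2.95 in an LRFI pig at day 2, was also the lowest of all probes and arrays. The LRFI values thus lie at the low end of the scale, and a limit from weak signal was not judged. Averaged over 5 samplings it stood at -1.75 ± 0.50 in LRFI and 0.15 ± 0.29 in HRFI pigs (n = 6 each), a difference of -1.91 (SE 0.21, limma adjusted p = 0.00196). F12 stood at 0.33 ± 0.11 against 0.64 ± 0.06 (-0.31, SE 0.05, adjusted p = 0.0239), and IL18R1 at -0.90 ± 0.04 against -1.04 ± 0.05 (0.15, SE 0.03, adjusted p = 0.0492). For each of these 3 genes every pig of 1 line lay beyond every pig of the other. Among unnamed probes, A_72_P666610 was lower in LRFI pigs by -2.02 and A_72_P487498 higher by 1.34. In total 116 probes differed, 60 higher and 56 lower in LRFI pigs. The lines did not overlap in 103 of them, which the choice of these probes by p value favours. Over all probes 344 (1.04%) showed no overlap, where chance gives 0.216% on average over splits. Called counts varied widely between single splits of the pigs, so 1 split may lie far from that average.

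Monocyte markers were higher in LRFI pigs as a list, with a median difference of 0.13 (camera adjusted p = 0.00055, and adjusted p = 0.330 with an estimated correlation; fry adjusted p = 0.0892). None of the 7 passed over all probes and 3 did adjusted over the list alone. CD163 differed by 0.30 (adjusted p = 0.214), FCN1 by 0.17 (0.167) and LYZ by 0.17 (0.475). The glucocorticoid list had a median of 0.13 (camera adjusted p = 0.0953), with 0 of 4 genes over all probes and 2 higher adjusted over the list alone. The immediate early, acute phase, antioxidant and hormone signalling lists had a median, mean and test that differed in sign, with medians of 0.02, -0.01, -0.02 and 0.01. The count was 57, 40, 42 and 63 without HRFI pigs 3394, 4323, 4325 and 4462, and 38, 76, 47 and 53 without LRFI pigs 3357, 3371, 4381 and 4420. CAPNS1 passed with each pig left out (highest adjusted p 0.00832). Pens were unevenly shared, with 4 of 6 HRFI pigs in pens 1 to 4 and 4 of 6 LRFI pigs in pens 15 to 18. With pen block as a covariate 59 probes passed, 46 of them among the 116. CAPNS1 then differed by -1.75 (adjusted p = 0.00262), and F12 (0.0567) and IL18R1 (0.102) no longer passed.

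**Figure D3:**
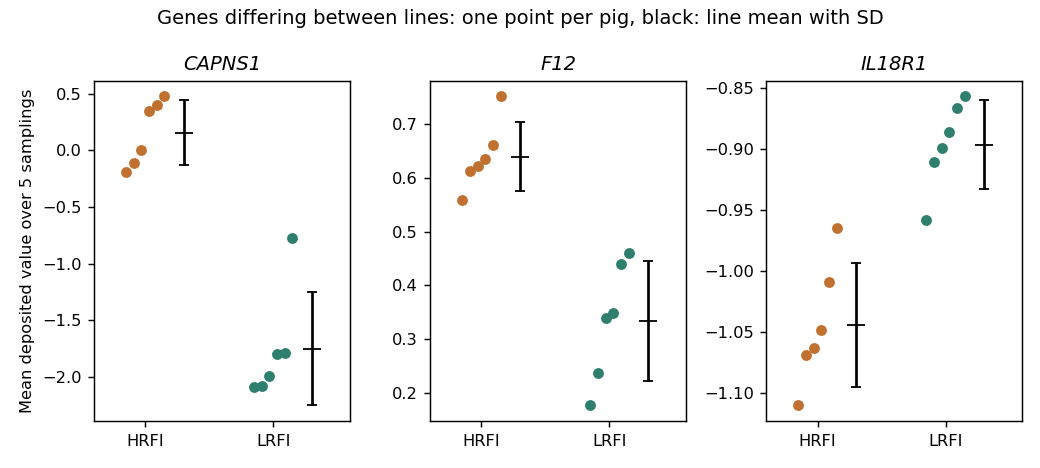
Mean deposited value over 5 samplings (vertical axis, array SD units) of CAPNS1, F12 and IL18R1, with 1 point per pig and black bars for the mean and SD of 6 HRFI and 6 LRFI pigs. LRFI pigs lie below HRFI pigs for CAPNS1 and F12 and above them for IL18R1, without overlap.

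At day -5 alone, before heat, CAPNS1 was the 1 named gene among 24 probes that differed between lines, 12 in each direction. It was lower in LRFI pigs by -1.76 (SE 0.27, limma adjusted p = 0.0238, 6 pigs per line). Monocyte markers had a median of 0.10 and T cell markers of 0.09 (camera adjusted p = 0.0601 each), and the interferon and antioxidant lists had a median and mean of opposite sign. Without HRFI pigs 3394 and 4323 the count was 15 and 9, without LRFI pigs 3371 and 4420 it was 11 and 5, and CAPNS1 did not pass without 7 of the 12 pigs (adjusted p up to 0.0773).

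Whether the lines changed differently was tested directly. Eosinophil genes gained more from 09:00 to 13:00 in LRFI than in HRFI pigs by point estimate, CCR3 by 0.26 (limma adjusted p = 1.00) and ALOX15 by 0.23 (1.00). A further member of their list changed by -0.02 in each line. The list's median change was 0.30 in 4 LRFI pigs and 0.01 in 5 HRFI pigs. The difference had a median of 0.25 (camera adjusted p = 0.000191, and adjusted p = 0.0777 with an estimated correlation; fry adjusted p = 0.481), with 0 of 4 genes passing over all probes and 3 adjusted over the list alone. From 09:00 to 18:00 the list's difference had a median of 0.22 (camera adjusted p = 0.00651, and adjusted p = 0.329 with an estimated correlation), with 0 genes by either count, and without a block for pig it reversed to -0.049 (camera adjusted p = 0.657). Interferon-stimulated genes differed by a median of -0.12 from 09:00 to 13:00 (camera adjusted p = 0.00503, and adjusted p = 0.516 with an estimated correlation), with 0 of 11 genes by either count. No probe passed in any test of the lines' changes with limma: 0 over all samplings (340 at an unadjusted p under 0.05, smallest adjusted p 0.0589), 0 for 13:00 against 09:00 (416), 0 for 18:00 against 09:00 (457), 0 for day 1 against day -5 (802) and 0 for day 2 against day -5 (434). These unadjusted counts are 1.03%, 1.26%, 1.39%, 2.44% and 1.32% of all probes. Each lies below the share of 0.05 that chance gives on average, so they are no sign of remaining differences. Why they lie below it was not tested. The named genes ranking highest over all samplings were THRA, PDE3A and ENG (limma adjusted p = 1.00 each). For the change to 13:00 they were ABCG2 (-0.28), ENG (0.22) and CCR3, and for that to 18:00 VTN (-0.15), CCR3 (0.26) and ALOX15 (0.23). For day 1 they were PTH1R (-0.44), TLR6 (0.15) and CD47 (0.11), and for day 2 CCR2 (0.13), CXCL8 (0.41) and CYSLTR2 (-0.19). Median, mean and test differed in sign for the neutrophil list at 18:00, the lipid list at days 1 and 2 and the glucocorticoid list at day 2, none of them passing camera.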

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

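The splits of pigs and samplings and the slopes between repetitions were planned before their results were seen; every other test of an explanation here was chosen after the result was seen.

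Single pigs stood far from the rest of their line in 5 gene values, each judged by the gap to the next pig over the range of the group. LRFI pig 4370 had changes of 0.74 for SH2D1A, -0.54 for HBE1 and -0.66 for MMP9 at day 2. HRFI pig 4447 had a day 2 change of 0.026 for TRO, and LRFI pig 3357 a mean CAPNS1 level of -0.77. Among arrays, HRFI pig 4325 at 13:00 and LRFI pig 4370 at day 2 had the lowest mean correlation with all other arrays in their groups, 0.968 each. Chance marks about 1 group in 20 in this way, and 7 of the 124 groups examined were marked where 6.2 would be by chance.

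The lines' changes differed by camera for 2 lists in 3 results. The interferon-stimulated genes differed by a median of -0.12 from 09:00 to 13:00, with a median change of -0.06 in LRFI and 0.01 in HRFI pigs. Eosinophil and basophil markers differed by 0.25 from 09:00 to 13:00 and by 0.22 from 09:00 to 18:00. None of the 3 differences passed camera with an estimated correlation, and the one to 18:00 reversed to -0.049 without a block for pig.

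The first pattern weighed is the change between the unheated samplings, 8831 probes from day -5 to 09:00 of day 0. Most pigs changed repetition label between them. In the 3 pigs with 1 label at both samplings, the change on the probes called in the other pigs had the same direction for 67.6% to 74.1% of 7562 probes, with slopes of 0.363 (HRFI pig 4447), 0.442 (LRFI pig 4307) and 0.845 (LRFI pig 4370). The bound set in advance against a repetition effect, a slope over 0.5 in each pig, was met by 1 of the 3. The bound set in advance for a repetition effect, a slope under 0.2 in each, was met by none, so by the planned bounds the slopes decide nothing. In the pigs that switched label, each left out in turn, slopes ran from 0.404 (HRFI pig 4325) to 1.11 (LRFI pig 4381). Only a reading made after the result was seen argues against repetition as the whole source. It rests on the absence of slopes under 0.2 and on 9499 probes passing with repetition as a covariate. A partial contribution stays open. With slide as a covariate 8426 probes passed, but slide explained a median of 2.04% of a probe's variance where chance gives 12.2%, as in values already adjusted for slide, so this decides nothing; the design names no biological difference between these samplings other than days and hour, so no biological explanation was tested.

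The second pattern is the low CAPNS1 signal of LRFI pigs. A sequence variant under the probe needs a line difference that stays the same over time, and the largest of its 4 tested changes was -0.26 (SE 0.23, limma adjusted p = 1.00), which does not argue against a variant. A variant carried alike by every LRFI pig also needs these pigs to share 1 level: 5 of them lay between -2.09 and -1.79 and pig 3357 at -0.77. Those 5 lie at the low end of the scale, so a shared level cannot be told apart from a floor of the signal. A difference in expression between the lines was not tested and would pass the same test over time, so a variant cannot be told apart from it. CAPNS1 was not alone: among the 116 called probes, 21 others had an absolute r over 0.9 with it over 12 pig means. Their choice by line difference favours this. Unnamed probes A_72_P671275 (-1.88 in LRFI, -0.05 in HRFI pigs) and A_72_P036051 (-1.70 and 0.14) had similar levels. Which genes these probes read is unknown, so they do not decide between the explanations.

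The third pattern is the day 13 fall of PPARG, BMPR1B and ACR, with a mean change of -0.91. With repetition as a covariate it was -1.05, which argues against a repetition effect as its source. A lower share of red cell RNA could contribute: over 12 pigs, the day 2 change of these genes correlated with that of HBE1 and ADIPOR1 (r = 0.861, permutation p = 0.00049; rho = 0.713, permutation p = 0.0114), within HRFI pigs at 0.926, within LRFI pigs at 0.847, and at 0.783 over the 8 pigs with 1 repetition at both samplings. Without the 2 pigs farthest from the median r was 0.593, and the set was cut to this pair after a set of 3 genes had given a weaker relation that rested on those pigs, so red cell share cannot be told apart from other sources. A response to prolonged heat, or to age, stays open and untested.

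For most counts only the real split reached the real count, which argues against chance. Shuffling samplings within pigs 100 times gave at most 1 probe against the real 18432 for any change over time, so 1 of 100 splits, the real one, reached it. Swapping the samplings compared within pigs, 1 of 100 splits, again the real one, reached the real count against day -5 at 09:00 (8831, highest other 6740), 13:00 (5832, 3883), 18:00 (4906, 996), day 1 (2325, 1272) and day 2 (3686, 1163), and 1 of 32 did at day 13 (9385, 6546). Against 09:00 of day 0 this was 1 of 100 at 18:00 (1379, 265), day 1 (8315, 5402) and day 2 (5843, 4121). At 13:00 it was 3 of 100 (45, 512), and the split with 512 points to a structure of the samples that was not looked into. Since other splits exceeded 45, chance is not excluded for this count. For day 13 against 09:00 the 8 splits are too few for a share under 0.05 (2727, highest other 1138, 1 split as large). Among splits of the 12 pigs into 6 and 6, 1 of 100, the real one, reached the line count at day -5 (24, highest other 3). For the lines over 5 samplings 3 of 100 splits were as large (116), the real one included. That share is under 0.05, but other splits exceeded the real count, so chance is not excluded for it. For the lines 1 other split called 7404 probes, which points to a structure of the samples that was not identified. It nearly repeats the pen blocks, with LRFI pig 4307 in place of HRFI pig 4447 among the 6 pigs of pens 1 to 4, though the pen blocks themselves called 0 probes with limma (3304 at an unadjusted p under 0.05). For the differences between the lines' changes the splits decide nothing, since a real count of 0 is reached by any split, here 100 of 100. The highest others were 4504 over all samplings, 1 at 13:00, 0 at 18:00, 2073 at day 1 and 1373 at day 2, and the largest of these again point to a structure among the pigs that was not identified.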

How the results depend on the processing

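Alternatives added after the data were examined were the omission of the 2 least correlated arrays (LRFI pig 4370 at day 1 and HRFI pig 4325 at day -5), repetition removed before pig means, 1 repetition with only the compared samplings, and pen block. No gene taken by the naming rule changed direction, in the comparison that named it, under any alternative. Genes of the line-by-time tests and uncalled list members given as values were not followed in this way. Median centring or trended and robust variances left every count within 1.5 times the reported one. Scaling moved the median of all probes by at most 0.0108. Balance between directions moved more: the share of called probes that were higher was 46.6% after quantile normalization instead of 58.1% at day 1 against day -5 and 70.0% instead of 55.6% at 13:00 against 09:00, and after median centring 48.0% instead of 60.5% at day 2 and 33.7% instead of 45.1% at day 13 against 09:00. Unless stated, the cause of a change was not tested. The mean of all probes of a gene was not run, since each gene has 1 named probe. Further probes of these genes may stand among the unnamed ones. Background signal was not used, so limits from weak signal are unknown.

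Without a block for pig the counts were 3345 at 13:00, 2295 at 18:00, 481 at day 1 and 1479 at day 2 against day -5, 0 at 13:00, 487 at 18:00, 5111 at day 1, 2697 at day 2 and 300 at day 13 against 09:00, and 5004 for the lines, where arrays of 1 pig then counted as separate animals. The eosinophil and basophil difference between the lines' changes to 18:00 reversed to -0.049 (camera adjusted p = 0.657). With pig as a random block 1379 probes passed for the lines and 1 for line by time. With slide as a covariate 2108 passed at 18:00 against 09:00, and with repetition 7077 at day 2 against day -5, and 3630 and 1575 at days 2 and 13 against 09:00. For the lines, 200 passed with slide effects removed, 60 with only 18:00, day 1 and day 2, and 59 with pen block. With only the arrays compared, fewer samples estimated the spread, and 2891 passed at 09:00, 1946 at 13:00, 1454 at 18:00, 0 at day 1 (limma), 1565 at day 2 and 4122 at day 13 against day -5, and 5 at 13:00, 335 at 18:00 and 0 at day 13 against 09:00. Within 1 repetition, with fewer arrays, 9 passed at 13:00 against 09:00, 804 at day 1, 1173 at day 2 and 1 for line by 18:00; with only the compared samplings too, limma called 1 at 13:00 (2928 at an unadjusted p under 0.05), 0 at 18:00 (5881), 0 at day 1 (4273) and 158 at day 2. Quantile normalization gave 90 at 13:00 against 09:00. Without the lowest probes 66 passed for the lines and 1 for line by time. Array weights (0.129 to 3.35) gave 2352 at 13:00, 4964 at 18:00, 12614 at day 1, 11694 at day 2 and 8566 at day 13 against 09:00, and 1 for line by time. Without the 2 least correlated arrays 522 passed at day 1 and 2332 at day 2 against day -5. With the 340 named probes alone, fewer tests, 170 passed for any change, 106, 68, 53, 28, 44 and 107 against day -5 in order of time, 4, 21, 63, 62 and 28 against 09:00, 8 for the lines and 6 at day -5. With an estimated correlation 0 of 21 list calls by camera held.

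Leaving out each pig gave 14090 to 18993 for any change, 6420 to 8530 at 09:00, 3715 to 6418 at 13:00, 3410 to 5038 at 18:00, 273 to 3602 at day 1, 1650 to 4485 at day 2 and 6679 to 10004 at day 13 against day -5. Against 09:00 it gave 5 to 409 at 13:00, 92 to 1893 at 18:00, 6131 to 8389 at day 1, 3533 to 6027 at day 2 and 8 to 6869 at day 13. It gave 38 to 131 for the lines, 5 to 33 at day -5, 0 to 0 for each difference between the lines' changes and 14 to 29 list calls. Of the named genes, those called with each pig left out numbered 18 of 28 at 09:00, 9 of 18 at 13:00, 8 of 17 at 18:00, 1 of 16 at day 1, 8 of 22 at day 2 and 18 of 29 at day 13 against day -5, and 0 of 13 at day 13 against 09:00.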

Other observations

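NR3C1, the glucocorticoid receptor, was lower at 09:00 than at day -5 by -0.11 (SE 0.03, limma adjusted p = 0.00120) in 9 of 9 pigs and at 13:00 by -0.08 (adjusted p = 0.0137) in 9 of 12. Against 09:00 it was higher at day 1 by 0.13 (adjusted p = 0.000277) and at day 2 by 0.10 (adjusted p = 0.00525), in 8 of 9 pigs each. The thyroid hormone receptor THRA rose by 0.07 at 18:00 against day -5 (adjusted p = 0.0192, 11 of 12 pigs) and fell by 0.07 from 09:00 to day 1 (adjusted p = 0.0144, 9 of 9). The adiponectin receptor ADIPOR2 stood 0.13 above day -5 at 09:00 (adjusted p = 0.0281, 6 of 9), and ADIPOR1 was lower by -0.33 at day 13 (adjusted p = 0.000255, 6 of 6) and by -0.32 at day 13 against 09:00 (adjusted p = 0.00737, 3 of 4). As a list these 4 genes passed camera in no comparison.

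CD3G, a chain of the T cell receptor complex, rose against day -5 by 0.08 at 09:00 (SE 0.03, limma adjusted p = 0.0403, 6 of 9 pigs), by 0.11 at 13:00 (adjusted p = 0.00506, 11 of 12) and by 0.11 at 18:00 (adjusted p = 0.00849, 11 of 12), and differed by 0.01 at day 1 (adjusted p = 0.794). CD8A was higher than at 09:00 by 0.19 at day 1 (adjusted p = 0.0112, 8 of 9) and 0.17 at day 2 (adjusted p = 0.0339, 9 of 9). CD4 was called in none of these comparisons. The early activation marker CD69 rose by 0.19 at 09:00 (adjusted p = 0.000948, 7 of 9) and by 0.14 at 18:00 (adjusted p = 0.0144, 9 of 12). CTSK, which encodes a lysosomal protease, was lower than day -5 by -0.24 at 09:00 and -0.17 at 13:00 (adjusted p = 0.00234, 11 of 12), and differed by 0.01 at day 1 (adjusted p = 0.942). CD69, CD8A and CTSK were followed here because of their values in other comparisons.

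The repetition label had its own signature. With pig, line and time in the model, 7021 probes differed between repetitions, 3123 higher and 3898 lower in repetition 2, and 73 of them were named. The anti-inflammatory cytokine IL10 was lower in repetition 2 by -0.23 (limma adjusted p = 0.00350), ICOS by -0.14 (adjusted p = 0.00306), and HBE1 was higher by 0.21 (adjusted p = 0.00409). Genes with large changes at days 2 and 13 differed too, PPARG by 0.34 (adjusted p = 0.0156), BMPR1B by 0.33 (0.0133) and ACR by 0.32 (0.00872), all higher in repetition 2, and LYZ was lower by -0.17 (0.0202). What the label stands for is not stated.

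Individual differences made up a large part of the spread. Pig explained a median of 33.1% of a probe's variance over the 75 arrays (14.9% by chance), sampling 15.5% (8.11%), line 1.90% (1.35%) and slide 2.04% (12.2%). Each pig belongs to 1 line, so the share of pig contains that of line. Slide's share lay below chance, as in values already adjusted for slide, so pig cannot be ranked against slide or line. For 57 of 75 arrays the most similar other array came from the same pig. Of the 116 probes that differed between lines, 14 did so by more than 1 unit, CAPNS1 among them.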
